A study of Mus musculus with 9 samples.

How the data were processed

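RNA was extracted with Trizol from the striatum of cGAS KO, STING KO and wild-type mice, and polyadenylated RNA was made into libraries and sequenced as paired reads on an Illumina HiSeq instrument, per the labels' protocols. The knockouts were made with CRISPR-Cas9, per the labels. HISAT2 (a spliced aligner), featureCounts (a read counter) and the mm10 genome build are named in the submitters' processing notes. Their versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here, so genes that overlap, have antisense partners or have near-identical copies are uncertain. The deposited values are whole-number counts per gene, 1 file per sample, with no normalization by the authors as far as the values show.

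The files list the same 54532 Ensembl gene IDs. Of these, 54495 matched GENCODE M21 on GRCm38, the assembly that mm10 names, and the 37 without a match held at most 0.036% of a library's counts. Library totals ranged from 14129021 to 21286775 counts. A floor of 3 counts is 0.141 to 0.212 CPM at these depths, and floors cover counting error only. Groups and replicate numbers come from the sample labels. No pair of libraries within a group agreed within sampling noise in a chi-square test of their counts over genes.

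Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with all 9 libraries in 1 fit, TMM factors and genes kept by filterByExpr, which left 17821. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. CPM are TMM-normalized. The SE of a fold change was taken from its fold change and F statistic. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 34 lists with at least 5 tested members of the 37 lists fixed. Signs of a list's median, mean and camera direction differed in 10 of the 102 list tests, 0 of them called.

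The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the targeted genes, the 5 genes with the smallest p in each direction where fewer than 10 passed, and for each list up to 2 members with the highest mean CPM where none passed. The text gives some of the genes so named, and an item among them is not reported here. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, only the 6 libraries compared, the replicate number as a block, leaving out each library, stricter thresholds, and camera with an estimated correlation or fry for lists. DESeq2 was run without a count filter and adjusted over 31889 genes, so it differed from edgeR in the gene set as well as the test. Chosen after seeing the data were the fits without the 3 libraries of low complexity, with low complexity as a covariate, and limma-voom with library quality weights. These 3 libraries are the ones with the fewest genes with 1 to 9 counts.

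The methods were tested on simulated counts with the means, depths and dispersions of the real genes. Changed genes were drawn from those with a mean of at least 5 CPM. Each gene had the same dispersion in every library, so the 3 libraries of low complexity did not stand apart in the simulation. With all 9 libraries edgeR recovered 5% of genes changed 2-fold and 74% of genes changed 4-fold in cGAS KO against WT, 10% and 70% in STING KO against WT, and 11% and 71% in STING KO against cGAS KO. Without the 3 libraries of low complexity the shares were 68% and 100%, 63% and 100%, and 67% and 99%. Calls among unchanged simulated genes numbered 4, 5 and 5 with 9 libraries and 19, 15 and 13 without those 3. Fold changes against the shared WT libraries were compared with 20 simulated draws without any effect.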

Results

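Messenger RNA was measured by sequencing in 9 striatum libraries of mice on a C57BL/6J background, 3 from animals lacking cGAS (cGAS KO), 3 from animals lacking STING (STING KO) and 3 from wild-type animals (WT). The striatum is the input nucleus of the basal ganglia, and the series describes the brains as taken after ischemic stroke. cGAS is the enzyme that senses DNA in the cytosol and makes the messenger cGAMP, and STING is the membrane receptor that binds cGAMP and starts an interferon response. The comparisons ask how the brain transcriptome differs when either protein is missing. Libraries from uninjured animals were not analysed here, and no time after the stroke is given in the sources used here, so each comparison is between genotypes. Library totals ranged from 14129021 to 21286775 counts over 54532 gene IDs. Below, a level is the mean of TMM-normalized counts scaled to library size (CPM) ± SD over the 3 libraries of a group, unless stated otherwise. The labels do not say that the replicates are separate animals, so the p-values measure the spread between these libraries.

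In each group 1 library stood apart from the others. cGAS KO replicate 2, STING KO replicate 2 and WT replicate 3 held 2280 to 4723 genes with 1 to 9 counts, against 7096 to 7927 such genes in the other 6 libraries. Brought to equal depth, these 3 libraries had 19741 to 22164 genes with a count, against 23443 to 24639 in the other 6. Ribosomal protein transcripts took 0.663%, 0.508% and 0.289% of their counts, against 0.75% to 0.962% in the other 6. The first principal component, with 49.4% of the variance, separated them from the rest. They are called the libraries of low complexity below, a division made after the data were seen. The biological coefficient of variation was 38.8% over all 9 libraries and 17.2% over the other 6.

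**Figure D1:**
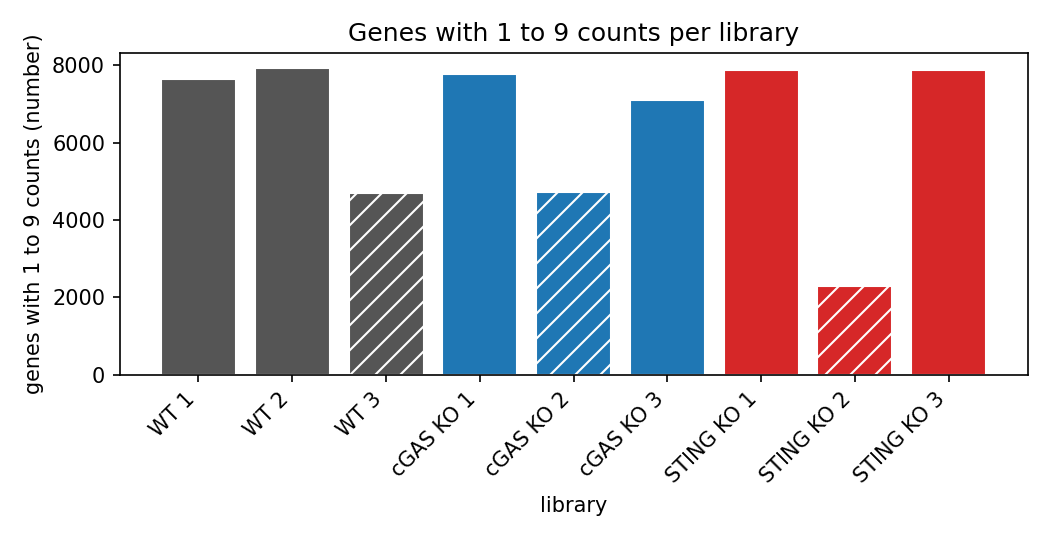
Number of genes with 1 to 9 counts (y axis) in each of the 9 libraries (x axis), coloured by group (grey WT, blue cGAS KO, red STING KO). The hatched bars are WT replicate 3, cGAS KO replicate 2 and STING KO replicate 2, which lie between 2280 and 4723, below the 7096 to 7927 of the other 6 libraries.

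The targeted genes were transcribed at a low level in every group. Cgas (ENSMUSG00000032344, chromosome 9, 78430526 to 78443237, minus strand, GRCm38) was at 1.10, 0.377 and 0.262 CPM in the cGAS KO libraries, at 1.55, 1.05 and 1.45 CPM in the STING KO libraries and at 1.40, 2.63 and 3.18 CPM in the WT libraries. Its log2 fold change in cGAS KO against WT was -2.02 with an SE of 0.63, and no cGAS KO library reached the lowest WT library. By edgeR's quasi-likelihood test this did not pass the threshold over all genes (unadjusted p = 0.0104, adjusted p = 0.9999). Sting1 (ENSMUSG00000024349, chromosome 18, 35733679 to 35740554, minus strand) was at 2.18, 1.05 and 1.85 CPM in the STING KO libraries, at 2.67, 1.66 and 2.75 CPM in the cGAS KO libraries and at 4.06, 3.01 and 1.34 CPM in the WT libraries. Its log2 fold change in STING KO against WT was -0.73 with an SE of 0.50, and the libraries overlapped. A CRISPR-Cas9 knockout can leave the transcript in place, and the edited exons are not given in the sources used here, so whole-gene counts are a weak check of these labels.

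In the striatum of cGAS KO mice, transcripts of ribosomal proteins, of medium spiny neurons and of interferon gamma response genes were higher as groups than in WT by camera with a preset correlation, while edgeR called no single gene. With an estimated correlation each of these 3 lists had an adjusted p = 0.900, and the medium spiny neuron call was also lost without the 3 libraries of low complexity (median 0.06, adjusted p = 0.481). It was lost as well without WT replicate 3 alone (camera adjusted p = 0.656), the library in which these markers were low. Their mean log2 CPM was 7.21 there and 8.159 to 8.5 in the other libraries, those of low complexity included. WT replicate 3 also had the highest mean of the cortical and other non-striatal neuron markers (4.425). All 30 ribosomal protein genes had a positive fold change, with a median log2 fold change of 0.50. Rpl3, a protein of the large ribosomal subunit, was at 483 ± 73.0 CPM in cGAS KO and 293 ± 86.0 CPM in WT, and Rpl4 was at 364 ± 61.2 and 257 ± 108 CPM. Of 24 markers of striatal medium spiny neurons, the projection neurons of this region, 23 had a positive fold change with a median of 0.25. Adcy5, the main striatal adenylyl cyclase, was at 2281 ± 412 against 1738 ± 205 CPM. Of 15 interferon gamma response genes 13 had a positive fold change, and Irf8, a transcription factor of myeloid cells, was at 8.43 ± 0.82 against 5.67 ± 1.54 CPM.

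By camera with its preset correlation, 5 of the 34 gene lists tested rose in cGAS KO and 0 fell: ribosomal proteins (adjusted p = 1.47e-11), medium spiny neuron markers (adjusted p = 1.12e-05), interferon gamma response (median 0.49, adjusted p = 0.00602), cell cycle and proliferation genes (median 0.18, adjusted p = 0.0166) and erythrocyte and platelet markers (median 0.54, adjusted p = 0.0211). With an estimated correlation each of the 5 had an adjusted p = 0.900, and 0 lists were called. Without the 3 libraries of low complexity, the ribosomal proteins (median 0.29, adjusted p = 4.46e-09) and the interferon gamma response (median 0.39, adjusted p = 0.0213) kept their camera call. The cell cycle genes (median 0.08, adjusted p = 0.481) and the erythrocyte and platelet markers (median 0.07, adjusted p = 0.918) lost it, as did the medium spiny neuron markers. Called in that fit but not over 9 libraries were 4 lists. Mitochondrially encoded genes (median 0.30, adjusted p = 0.0376) and immediate early genes (median 0.20, adjusted p = 0.0204) were higher. The mean log2 CPM of the mitochondrial list, as scaled over 9 libraries, overlapped between the groups. It was 9.492 and 9.994 in cGAS KO replicates 1 and 3, and 9.216 and 9.681 in WT replicates 1 and 2. Fibroblast, meningeal and matrix genes (median -0.24) and choroid plexus markers (median -1.36) were lower, both with an adjusted p = 0.0346, and the choroid plexus list turned to higher in cGAS KO when WT replicate 1 alone was left out (adjusted p = 0.0296). Leaving out WT replicate 3 alone, which had the lowest ribosomal protein share, also ended the calls of the medium spiny neuron markers (adjusted p = 0.656), the cell cycle genes (adjusted p = 0.684), the erythrocyte and platelet markers (adjusted p = 0.583) and the interferon gamma response (adjusted p = 0.208). Leaving out cGAS KO replicate 3 ended the calls of the interferon gamma response, the cell cycle genes (both adjusted p = 0.0774) and the erythrocyte and platelet markers (adjusted p = 0.199). The last list also lost its call without cGAS KO replicate 2 (adjusted p = 0.0878) and with low complexity as a covariate (adjusted p = 0.0648), and the cell cycle genes without WT replicate 2 (adjusted p = 0.110). Adjusted over the list alone, 0 genes of any list passed in cGAS KO against WT.

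Over the 17821 genes tested, edgeR called 0 genes in cGAS KO against WT, and 361 had an unadjusted p under 0.05, where 891 would by chance. DESeq2, over 31889 genes without a count filter, called 1 gene, Baiap3. By limma-voom 0 were called, or 4 with library quality weights, an alternative chosen after the data were seen. The genes with the smallest p in this comparison are given as values, and none passed in edgeR. Baiap3 (chromosome 17, 25242659 to 25256364), a regulator of dense-core vesicle trafficking, was at 32.9 ± 3.75 CPM in cGAS KO and 14.4 ± 2.12 CPM in WT, a log2 fold change of 1.19 with an SE of 0.20. Its edgeR unadjusted p was 0.000184, and its DESeq2 adjusted p was 0.0115, in a range of 0.0115 to 1 over the alternatives. Zfpm1, a cofactor of GATA transcription factors, was at 58.0 ± 11.5 against 33.5 ± 3.98 CPM, and Lrrc4b, a synaptic adhesion protein, at 266 ± 64.8 against 151 ± 13.6 CPM. Zfp622 was at 42.2 ± 9.92 against 22.5 ± 5.96 CPM and Frat1, a GSK-3 binding protein, at 15.1 ± 2.38 against 7.97 ± 1.67 CPM. On the lower side were Robo3, an axon guidance receptor, at 17.9 ± 7.85 against 50.2 ± 7.07 CPM, and Npr3, the natriuretic peptide clearance receptor, at 1.61 ± 0.66 against 7.52 ± 4.72 CPM. Pnpt1, a mitochondrial RNA-degrading enzyme, was at 15.2 ± 3.02 against 25.1 ± 2.40 CPM, Gk, glycerol kinase, at 16.1 ± 3.01 against 27.2 ± 5.07 CPM, and the noncoding RNA Gm40841 at 11.9 ± 1.54 against 23.2 ± 7.13 CPM. In 8.0% of genes the 3 cGAS KO libraries did not overlap the 3 WT libraries, where chance gives 10%.

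In the striatum of STING KO mice, immediate early genes, the transcripts that neurons and other cells make within minutes of stimulation, were higher as a group than in WT by camera with a preset correlation. With an estimated correlation the list was not called (adjusted p = 0.386), nor by fry (adjusted p = 0.459). Of the 22 members, 21 had a positive fold change, with a median log2 fold change of 0.97. Arc, an activity-regulated synaptic protein (chromosome 15, 74669083 to 74672570), was at 260 ± 113 CPM in STING KO, 84.4 ± 11.3 CPM in WT and 83.4 ± 7.47 CPM in cGAS KO. Fos was at 29.3 ± 16.8, 6.72 ± 1.34 and 6.78 ± 1.44 CPM in the same order, and Fosl2 at 61.2 ± 4.37, 22.7 ± 6.71 and 40.4 ± 6.32 CPM, both subunits of the AP-1 transcription factor. The 2 members with the highest mean level, Egr1 and Egr3, were at 475 ± 158 and 236 ± 36.0 CPM in STING KO and at 250 ± 74.2 and 157 ± 6.53 CPM in WT.

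**Figure D2:**
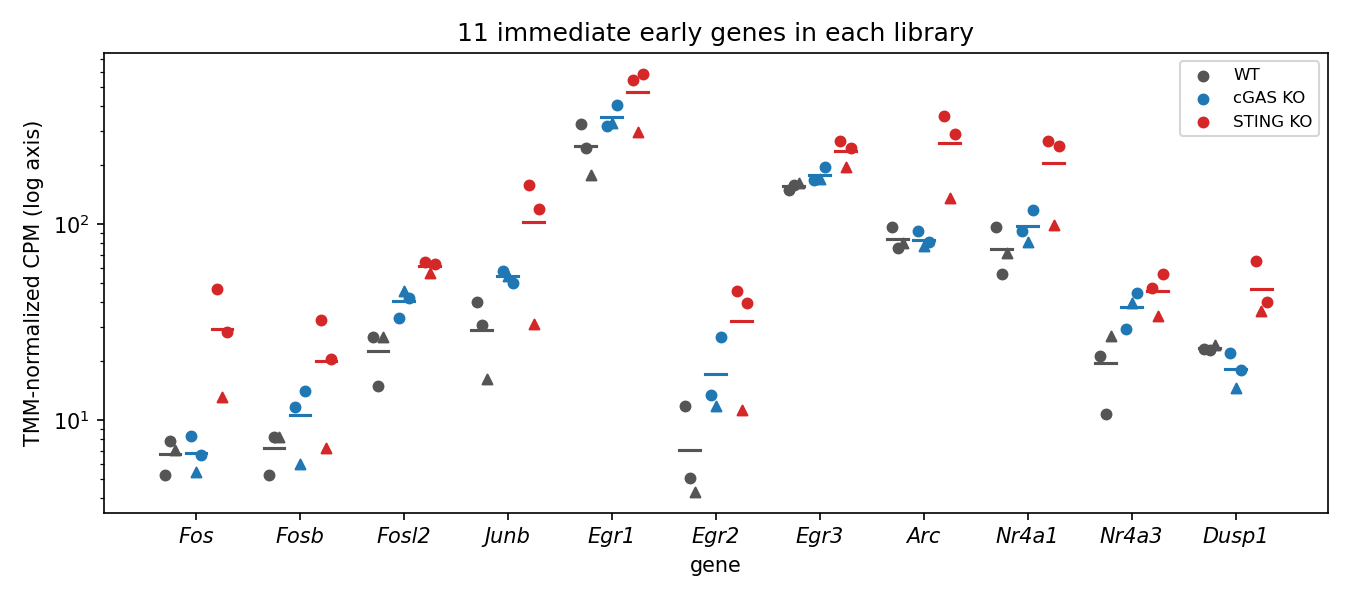
TMM-normalized CPM (log axis) of the 11 immediate early genes that passed when adjusted over the list alone in STING KO against WT, in each library of WT (grey), cGAS KO (blue) and STING KO (red). Triangles mark the libraries of low complexity and horizontal lines the group means; Arc is at 136 to 356 CPM in STING KO and at 75.8 to 97.3 CPM in WT.

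Camera with its preset correlation called the immediate early genes higher in STING KO (adjusted p = 2.20e-19), a call lost with an estimated correlation (adjusted p = 0.386). The preset call held without each library in turn and without the 3 libraries of low complexity (median 1.30, adjusted p = 3.57e-21). Without those libraries the cortical and other non-striatal neuron markers had a median of 0.37, which camera did not call (adjusted p = 0.118). Over all genes tested, edgeR called 0 of the immediate early genes. Adjusted over the list alone, 11 members passed, all higher: Fos, Fosb, Fosl2, Junb, Egr1, Egr2, Egr3, Arc, Nr4a1, Nr4a3 and Dusp1. Over the other 6 libraries, 17 members passed over the list alone, and edgeR called 2 of them over all genes, Arc (log2 fold change 1.90, SE 0.18, adjusted p = 0.0283) and Junb (log2 fold change 1.98, SE 0.19, adjusted p = 0.0283). Over the alternatives the adjusted p of Arc ranged from 0.00051 to 1 and that of Junb from 0.00269 to 1. Members other than Egr1, Egr3, Arc and Fosl2 are named after their values were seen. STING KO replicate 2, of low complexity, had the lowest value of the 3 STING KO libraries for each of these 11 genes. Its mean log2 CPM over the whole list was 4.005, against 5.58 and 5.27 in STING KO replicates 1 and 3. That mean lay within the 3.77 to 4.107 of the WT libraries and below the 4.083 to 4.433 of the cGAS KO libraries. The rise of the list mean thus rests on STING KO replicates 1 and 3, though the 3.77 is from WT replicate 3, also of low complexity. Single members differed. In STING KO replicate 2 Arc was at 135.5 CPM (WT 75.76 to 97.27), Fos at 13.17 (5.238 to 7.839) and Fosl2 at 56.25 (14.93 to 26.67). Egr3, Nr4a1, Nr4a3 and Dusp1 were also above every WT library there, while Fosb, Junb, Egr1 and Egr2 were not.

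Other lists that rose by camera in STING KO were the interferon gamma response (14 of 15 members positive, median 0.35, adjusted p = 3.82e-06), ribosomal proteins (28 of 30, median 0.29, adjusted p = 3.38e-05), MHC class I antigen presentation (13 of 15, median 0.38, adjusted p = 0.000512) and medium spiny neuron markers (22 of 24, median 0.16, adjusted p = 0.00284). With an estimated correlation their adjusted p was 0.386, 0.897, 0.691 and 0.897 in that order, and 0 were called. Fibroblast, meningeal and matrix genes fell (17 of 20 negative, median -0.33, adjusted p = 0.00257), and had an adjusted p = 0.400 with an estimated correlation. Fn1, fibronectin, was at 65.3 ± 6.44 CPM in STING KO and 103 ± 31.6 CPM in WT. Both immune lists hold Tap1 and Nlrc5. Their most abundant members differed by less than the spread between libraries: Gbp7, a guanylate-binding protein, was at 8.02 ± 2.78 against 6.39 ± 0.35 CPM, Irf8 at 6.97 ± 1.31 against 5.67 ± 1.54 CPM, and B2m, the light chain of MHC class I, at 30.3 ± 12.3 against 30.9 ± 19.1 CPM. Over the 6 libraries without low complexity the medium spiny neuron median turned to -0.15 (adjusted p = 0.0942), while the other 5 lists kept their call. The ribosomal protein median was then 0.13, with 21 of 30 members positive (adjusted p = 0.0196). Called lower in that fit but not over 9 libraries were oligodendrocyte and myelin markers (median -0.32, adjusted p = 0.000498), endothelial genes (median -0.21, adjusted p = 0.00209) and choroid plexus markers (median -2.04, adjusted p = 0.000129). The oligodendrocyte list overlapped between the groups in mean log2 CPM, as scaled over 9 libraries. It was at 7.098 and 7.883 in STING KO replicates 1 and 3, and at 8.178 and 7.638 in WT replicates 1 and 2. The choroid plexus marker Ttr was at 2487 CPM in WT replicate 1 and at 78.6 and 14.8 CPM in WT replicates 2 and 3, and leaving out WT replicate 1 alone turned that list to higher in STING KO (adjusted p = 0.00148). Leaving out WT replicate 3 alone turned the ribosomal proteins (adjusted p = 0.251) and the medium spiny neuron markers (adjusted p = 0.204) to lower in STING KO. In WT replicate 3 the mean log2 CPM of the medium spiny neuron markers was 7.21, against 8.159 to 8.5 in the other libraries. The medium spiny neuron call also ended without STING KO replicate 2 (adjusted p = 0.144), the ribosomal call without STING KO replicate 1 (adjusted p = 0.0732) and the MHC class I call without STING KO replicate 3 (adjusted p = 0.0637). The fibroblast call ended without STING KO replicate 3 (adjusted p = 0.160) or WT replicate 1 (adjusted p = 0.119).

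In the STING KO libraries, counts of the mitochondrial gene mt-Nd3, a subunit of respiratory complex I, were low and those of its nuclear copy Gm28438 high. mt-Nd3 (ENSMUSG00000064360, mitochondrial genome, 9459 to 9806) was at 3.65 ± 1.76 CPM in STING KO, 32.7 ± 15.7 CPM in WT and 48.1 ± 18.4 CPM in cGAS KO. Gm28438 (ENSMUSG00000101939, chromosome 1, 24612775 to 24613119), annotated as an unprocessed pseudogene, was at 36.0 ± 6.88, 3.09 ± 2.24 and 3.85 ± 1.79 CPM. Of the counts of both, the copy took 90.4% ± 5.22 (SD, n = 3) in STING KO, 7.53% ± 3.36 (SD, n = 3) in WT and 7.41% ± 1.95 (SD, n = 3) in cGAS KO. The pair is singled out after its values were seen. The summed counts of both had a log2 fold change in STING KO against WT of 0.15 (SE 0.40) over 9 libraries and -0.33 (SE 0.28) over the 6 without low complexity, and against cGAS KO of -0.39 (SE 0.40) and -0.60 (SE 0.28). The annotated transcripts differ at 1 of the 345 positions compared, T3C, counted from 1 at the 5′ end of mt-Nd3, with the mitochondrial base first, at position 9461 of the mitochondrial genome. Reads of the 2 genes are therefore hard to tell apart, and the counter's setting for reads with several matches is not given in the sources used here.

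**Figure D3:**
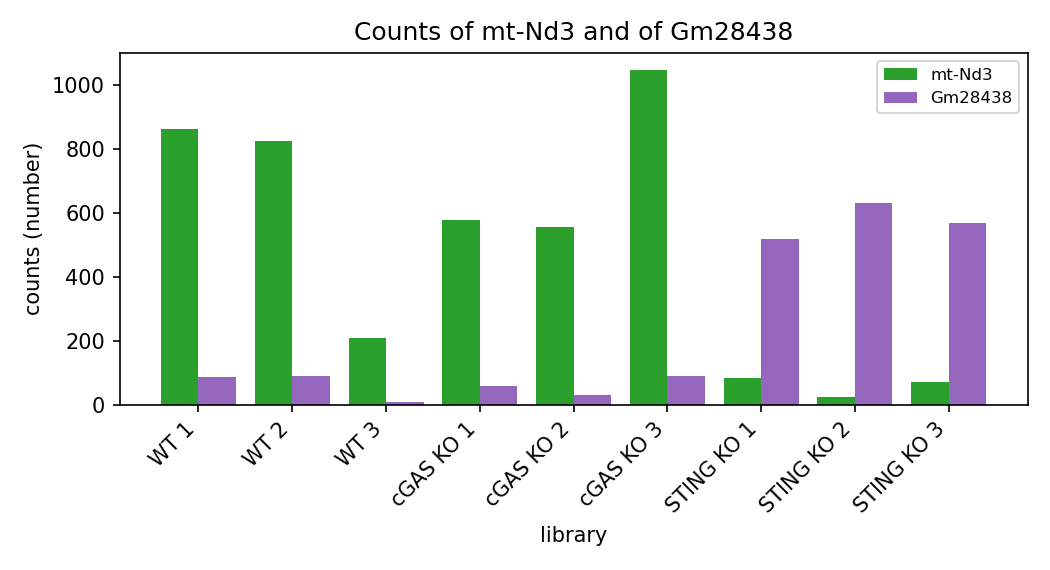
Counts (y axis) of mt-Nd3 (green) and of its nuclear copy Gm28438 (purple) in each library (x axis). In the 3 STING KO libraries mt-Nd3 has 25 to 84 counts and Gm28438 519 to 631, while in the other 6 libraries mt-Nd3 has 210 to 1049 and Gm28438 8 to 90.

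Over the 17821 genes tested, edgeR called 0 genes in STING KO against WT, and 291 had an unadjusted p under 0.05, where 891 would by chance. DESeq2, over 31889 genes without a count filter, called 10. Of these AC149090.1, Arc, Fos, Fosl2, Gm28438 and 1700016P03Rik were higher and mt-Nd3, mt-Tr, mt-Tg and Gm10600 lower. By limma-voom 0 were called, or 178 with library quality weights. Without a count filter edgeR called 4, AC149090.1, Gm28438, mt-Nd3 and Gm10600. Over the 6 libraries without low complexity edgeR called 4, with Gm28438, Arc and Junb higher and mt-Nd3 lower. For mt-Nd3 the log2 fold change was -3.16 with an SE of 0.52 over 9 libraries (edgeR adjusted p = 0.794) and -3.18 with an SE of 0.34 over 6 (edgeR adjusted p = 0.0462, in a range of 2.94e-06 to 1 over the alternatives). Other genes among the smallest p values, which did not pass in edgeR over the 17821 genes, were AC149090.1 on the unplaced scaffold JH584304.1 (1215 ± 169 CPM in STING KO, 229 ± 45.8 CPM in WT) and the noncoding 1700016P03Rik on chromosome 11 (19.5 ± 1.21 against 4.52 ± 1.75 CPM). The mitochondrial tRNA genes beside mt-Nd3 were also low, mt-Tr at 0.12 ± 0.12 against 3.17 ± 0.93 CPM and mt-Tg at 0 counts in all 3 STING KO libraries. Against a floor of 3 counts per library, mt-Tg was at least 7.0-fold lower in STING KO than the mean of WT. That mean came from 49, 27 and 4 counts in WT replicates 1, 2 and 3, the last near the floor itself. Gm10600 on chromosome 4, also at 0 counts in all 3 STING KO libraries, was at least 12-fold lower than the mean of WT, and Gm42528 on chromosome 5 was at 3.81 ± 1.42 against 11.2 ± 3.58 CPM. The share of genes whose libraries did not overlap was 7.07%, where chance gives 10%.

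Between STING KO and cGAS KO striatum, the immediate early genes had the largest median difference of the lists that camera called. All 22 members had a positive fold change in STING KO against cGAS KO, with a median of 0.76, and camera called the list (adjusted p = 4.95e-11), also without each library in turn. Without STING KO replicate 1 the list had a median of 0.44, with 19 of 22 members positive. With an estimated correlation it was not called (adjusted p = 0.697). Without the 3 libraries of low complexity its median was 1.08, and camera also called cortical and other non-striatal neuron markers higher (median 0.90, adjusted p = 0.0368). Adjusted over the list alone, Fos, Arc and Dusp1 passed, and over all genes 0 did in edgeR. In cGAS KO against WT, 14 of the 22 had a positive fold change, with a median of 0.22 that camera did not call (adjusted p = 0.0602), and 0.20 without the 3 libraries of low complexity, which it called (adjusted p = 0.0204). Dusp1, a phosphatase that turns off MAP kinases, was at 47.0 ± 15.7 CPM in STING KO and 18.2 ± 3.69 CPM in cGAS KO.

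Camera called 7 lists lower in STING KO than in cGAS KO, with medians of -0.32 for oligodendrocyte and myelin markers, -0.26 for homeostatic microglia markers, -0.25 for reactive astrocyte markers, -0.36 for mitochondrially encoded genes, -0.27 for pericyte and vascular smooth muscle markers, and -0.18 for both the ribosomal proteins and the endothelial and blood-brain barrier genes. Their adjusted p ranged from 0.00586 to 0.0263, and with an estimated correlation each had an adjusted p = 0.835, or an adjusted p = 0.697 for the pericyte list. The mitochondrial list holds mt-Nd3, whose counts were low in STING KO while those of Gm28438 were high. It was the 1 member that passed when adjusted over that list alone. The mean of the list was -0.54, with 11 of 13 members negative, and the list was not tested without mt-Nd3. Cst3, of the microglia list, was at 586 ± 382 CPM in STING KO and 521 ± 285 CPM in cGAS KO, and Gfap, the intermediate filament of astrocytes, at 105 ± 24.3 and 104 ± 24.1 CPM. These 2 were not lower, while 16 of 18 homeostatic microglia markers and 14 of 19 reactive astrocyte markers had a negative fold change. None of the 7 calls held without each library in turn. Without cGAS KO replicate 3 alone, which had the highest mitochondrial share (9.63% of counts), 6 of the 7 were lost, with the oligodendrocyte list the exception, and without STING KO replicate 2 also 6. Their adjusted p was then 0.0784 to 0.544 and 0.107 to 0.633. Leaving out cGAS KO replicate 1 ended the endothelial (adjusted p = 0.119), pericyte (0.0626), mitochondrial (0.106) and ribosomal (0.186) calls. Leaving out STING KO replicate 3 ended the endothelial (adjusted p = 0.0592) and pericyte (0.0673) calls, and STING KO replicate 1 the endothelial call (adjusted p = 0.0762). The oligodendrocyte call ended without cGAS KO replicate 2 (adjusted p = 0.126) or STING KO replicate 1 (adjusted p = 0.611). The pericyte call was lost with low complexity as a covariate (adjusted p = 0.0527). Over the 6 libraries without low complexity camera called 12 lists in place of 8, and the reactive astrocyte call was lost (adjusted p = 0.233). Called in that fit but not over 9 libraries were MHC class I genes (median 0.38, adjusted p = 0.00476) and the cortical neuron markers, both higher in STING KO. Medium spiny neuron markers (median -0.16, adjusted p = 0.00339), fibroblast genes (median -0.20, adjusted p = 0.00645) and infiltrating monocyte and macrophage markers (median -0.26, adjusted p = 0.0175) were called lower.

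**Figure D4:**
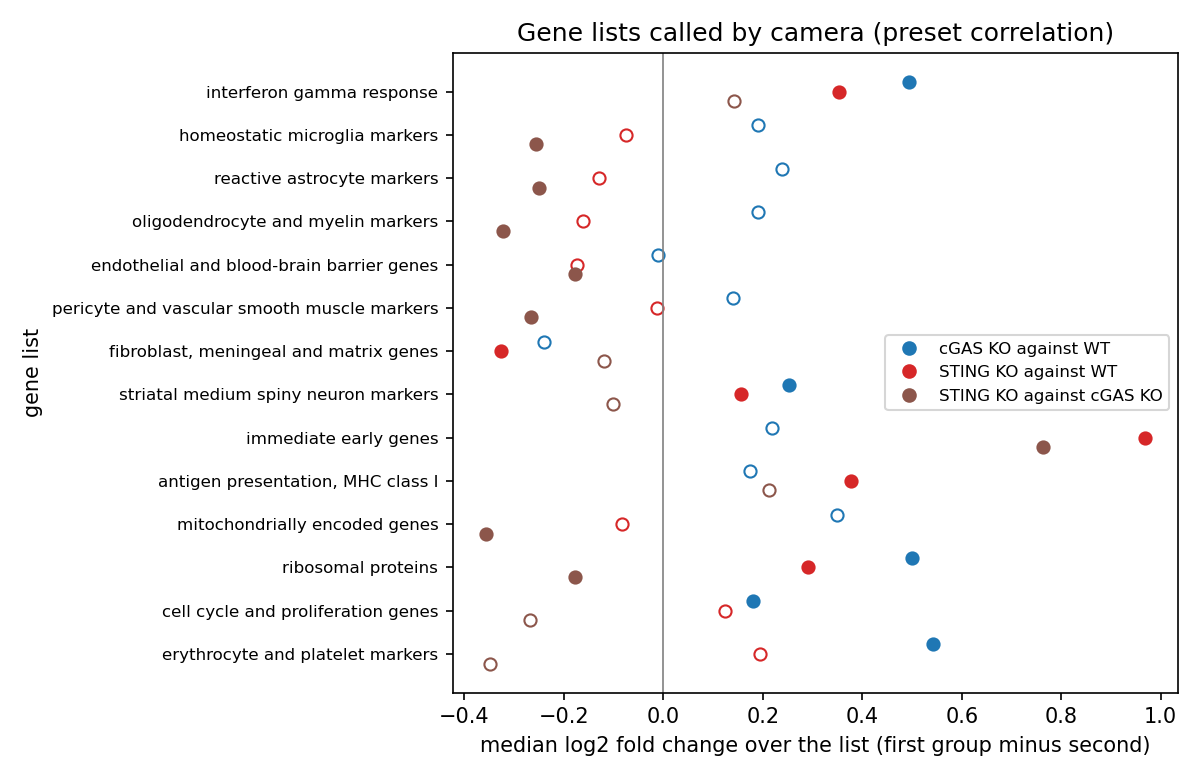
Median log2 fold change (x axis, first group minus second) of each gene list (y axis) that camera with a preset correlation called in at least 1 of the 3 comparisons, which are shown by colour. Filled points passed an adjusted p of 0.05 and open points did not; the immediate early genes lie at 0.97 in STING KO against WT and 0.76 in STING KO against cGAS KO.

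Over all genes, edgeR called 0 in STING KO against cGAS KO, with 258 at an unadjusted p under 0.05, where 891 would by chance. DESeq2, over 31889 genes without a count filter, called 8, with Arc, Fos, Dusp1 and Gm28438 higher and mt-Nd3, mt-Tr, mt-Tg and Gm10600 lower. By limma-voom 0 were called, or 29 with library quality weights. EdgeR without the 3 libraries of low complexity called 3, with Arc and Gm28438 higher and mt-Nd3 lower in STING KO. Without a count filter edgeR called 4, mt-Nd3, mt-Tr, mt-Tg and Gm28438. The log2 fold change of mt-Nd3 was -3.71 with an SE of 0.53. Slitrk6, a neuronal adhesion protein, was at 2.75 ± 0.15 CPM in STING KO and 6.36 ± 0.25 CPM in cGAS KO and did not pass (edgeR adjusted p = 1). The share of genes whose libraries did not overlap was 7.35%, where chance gives 10%.

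The genes of the pathway itself and its interferon targets did not pass in either knockout. Of 33 type I interferon response genes tested, 14 had a positive fold change in cGAS KO against WT (median -0.08, adjusted p = 0.607 by camera) and 20 in STING KO against WT (median 0.06, adjusted p = 0.446). Stat2, a transcription factor of interferon signalling, was at 26.4 ± 3.79 CPM in cGAS KO, 29.2 ± 1.98 CPM in STING KO and 30.4 ± 1.85 CPM in WT, and Cmpk2 at 24.9 ± 2.42, 23.7 ± 0.64 and 23.2 ± 0.72 CPM. The 16 tested components of the cGAS-STING pathway had medians of 0.04 and -0.07, and the kinase Tbk1 was at 43.0 ± 5.48, 46.9 ± 2.90 and 48.2 ± 2.77 CPM. Of 28 inflammatory cytokines and chemokines 10 were expressed enough to be tested, with medians of -0.35 and -0.40 and camera adjusted p = 0.601 and adjusted p = 0.252. Reactive microglia and phagocyte markers had medians of 0.19 and 0.16 (adjusted p = 0.273 and adjusted p = 0.446). Gfap was at 104 ± 24.1, 105 ± 24.3 and 96.4 ± 29.0 CPM in cGAS KO, STING KO and WT. These p values do not show that the groups were alike. In simulated data with the dispersions of the real genes, edgeR recovered 5% of genes changed 2-fold and 74% of genes changed 4-fold in cGAS KO against WT. In STING KO against WT it recovered 10% and 70%. The simulated changes were in genes with a mean of at least 5 CPM, so these shares do not cover genes at lower levels, Cgas and Sting1 among them.

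By edgeR, DESeq2 and limma-voom 0 genes were called in both knockouts against WT, and limma-voom with quality weights called 3, Baiap3, Zfpm1 and Lrrc4b, each higher. Across genes, the fold changes of cGAS KO and STING KO against the shared WT libraries had a correlation of 0.468, where simulated groups without any effect gave 0.492. Their covariance was 0.0975 against a simulated 0.165, a difference of -0.0676 over all 9 libraries and of 0.0169 over the 6 libraries without low complexity. In the simulated groups no library stood apart as the libraries of low complexity did, and only the mean of the 20 draws is given. The comparison therefore cannot decide whether the knockouts share an effect. Genes are not independent replicates, and with 3 WT libraries the controls could not be split with 2 in each part.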

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

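The tests of the immediate early genes without the 3 libraries of low complexity, the cortex and heat shock tests among them, and the counts of genes over other splits were chosen after the result was seen, while the counts of lists over other splits were not. Groups of 3 libraries were not tested for outliers. The gene lists below were picked out because the effects of the 2 knockouts against WT differed, by the camera test of STING KO against cGAS KO. Medians of log2 fold changes in that comparison were -0.26 for homeostatic microglia, -0.25 for reactive astrocyte, -0.32 for oligodendrocyte, -0.27 for pericyte and -0.36 for mitochondrially encoded genes, and -0.18 for both endothelial genes and ribosomal proteins. All 7 calls depend on single libraries and on the preset correlation. The mitochondrial list includes mt-Nd3, the gene that exchanged counts with Gm28438.

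The immediate early genes were higher in STING KO, by a median of 0.76 on the log2 scale against cGAS KO and of 0.97 against WT, calls that camera loses with an estimated correlation (adjusted p = 0.697 and adjusted p = 0.386). The tables argue against the libraries of low complexity as the source, since without them the median against WT was 1.30. Cortical markers had a median of -0.17 in STING KO against WT over 9 libraries, and without the 3 libraries of 0.37, not called by camera (adjusted p = 0.118), and of 0.90 against cGAS KO, called (adjusted p = 0.0368). More cortex in the STING KO dissections as the whole source is argued against, since in that fit the median of the immediate early genes with the cortical list as a covariate was 1.37 against WT, with a median SE of 0.25 over members, and 1.11 against cGAS KO. The limit is that few libraries set the slope of the covariate. STING KO replicates 1 and 3 had similar mean log2 CPM of the cortical list (3.96 and 3.82 as scaled over 9 libraries), so the slope came mostly from cGAS KO and WT. List members are not independent. A general stress response to handling stays open: the heat shock list had a median of 0.043 without the 3 libraries of low complexity, but its members went both ways, and Hspa1a and Hspa1b had log2 fold changes of 0.91 and 1.70. Genotype and injury stay open too, untested. In each STING KO comparison, loss of Sting1 cannot be told apart from other differences of the STING KO line. The exchange of counts between mt-Nd3 and Gm28438 in all its libraries may be 1 of these.

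Camera called 8 lists in STING KO against cGAS KO, and the highest count over the other splits of the same 6 libraries was 14. For cGAS KO against WT these counts were 5 and 18, and for STING KO against WT 6 and 15. Of 10 splits each, 5, 9 and 8 gave as many lists, the real split included. The 4 splits of each comparison that put the 2 libraries of low complexity on 1 side gave 6 to 14, 5 to 18 and 7 to 15 lists, and the other 5 splits besides the real split 1 to 8, 3 to 9 and 3 to 9. The highest counts thus point to a structure of the samples other than genotype, though not each such split exceeded the real count. For genes the real counts were 0, so that 10 of 10 splits give as many by construction, which says nothing about chance, and the highest of the other splits was 1 in STING KO against cGAS KO and 0 in both comparisons with WT. With 10 splits no share under 0.05 can be reached.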

How the results depend on the processing

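The fits without the libraries of low complexity, with low complexity as a covariate and with quality weights were chosen after seeing the data. Counts of called genes were 0 in the 3 comparisons under the scalings, the stricter filter and thresholds, limma-voom, only the 6 libraries compared, and without each library in turn (lowest 0, highest 0). In the order cGAS KO against WT, STING KO against WT and STING KO against cGAS KO, DESeq2 called 1, 10 and 8, no count filter 0, 4 and 4, the fit without the 3 libraries of low complexity 0, 4 and 3, low complexity as a covariate 0, 1 and 1, and limma-voom with quality weights 4, 178 and 29. In both knockouts against WT, quality weights called 3 genes and the others 0. The weights ran from 0.163 (WT replicate 3) to 4.42 (WT replicate 2) and were estimated from the same data. The cause of the differences was not tested. Another scaling moved the median of all genes by less than 0.1.

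List counts (5, 6 and 8) became 0, 0 and 0 with an estimated correlation and with fry, and 6, 8 and 12 without the 3 libraries of low complexity. Without each library in turn they ranged from 4 to 13, from 5 to 14 and from 2 to 8. The first was 8 without cGAS KO replicate 1, 11 without cGAS KO replicate 2 and 13 without WT replicate 1, the second 14 without WT replicate 3, and the third 2 without cGAS KO replicate 3 and 3 without STING KO replicate 2. Lists that turned direction, with camera adjusted p, were choroid plexus without WT replicate 1 (0.0296 in cGAS KO, 0.00148 in STING KO; over the alternatives 0.00196 to 0.970 and 0.000129 to 0.989). In STING KO against WT without WT replicate 3 they were medium spiny neurons (0.204), complement (0.0458), oxidative phosphorylation (0.010) and ribosomal proteins (0.251), and without the 3 libraries medium spiny neurons (0.0942). Their ranges over the alternatives were 3.00e-05 to 0.959, 0.0458 to 0.973, 0.000439 to 0.996 and 5.82e-09 to 0.959. Over the single libraries left out they were 0.0296 to 0.671 and 0.00148 to 0.980 for choroid plexus, and 0.0458 to 0.913 for complement. The cause was not tested. Of the other list comparisons, 1378 kept their side of the threshold, 63 gained and 79 lost a call. Of 6609 comparisons of named genes 73 gained a call and 0 turned a called direction. Signs changed with neither value past the threshold in 120 list and 421 gene comparisons, counted as kept.

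With the replicate block the counts of called genes were 0, 0 and 0 and those of lists 6, 6 and 8. Deviations of same-numbered libraries correlated between -0.447 and 0.502, 4 of 9 pairs were over 0.1, and 3 of 9 libraries correlated best with their own number. This cannot decide whether the numbers pair the samples, since low complexity dominated the deviations. The libraries of low complexity, replicate 2 in both knockouts and replicate 3 in WT, correlated with each other at 0.469 to 0.533. The pairs of replicate 1 correlated at 0.327 to 0.502.

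At these depths a floor of 3 counts is 0.141 to 0.212 CPM. Over 9 libraries edgeR recovered 5% to 11% of simulated 2-fold changes in genes with a mean of at least 5 CPM. Without the 3 libraries of low complexity it recovered 63% to 68%, and calls among unchanged genes rose from 4 or 5 to 13 to 19.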

Other observations

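The tests of mt-Nd3 were chosen after the result was seen, as was the bound of 3 on the odds ratio near Cgas. The tests of the 3 libraries of low complexity and the other tests near the targeted genes were not. Markers of choroid plexus, the tissue that makes cerebrospinal fluid, differed between single libraries. Ttr, transthyretin, was at 2487 CPM in WT replicate 1, at 322 CPM in STING KO replicate 2 and at 4.15 to 164 CPM in the other 7 libraries. Slc17a7, the glutamate transporter of cortical neurons, ranged from 47.3 CPM in WT replicate 1 to 823 CPM in WT replicate 3. Without the 3 libraries of low complexity, choroid plexus markers had a median log2 fold change of -2.04 in STING KO against WT and -1.36 in cGAS KO against WT (camera adjusted p = 0.000129 and adjusted p = 0.0346), with WT replicate 1 among the 2 WT libraries left.

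The next 6 lists were not called in either knockout against WT, with or without the 3 libraries of low complexity. Medians in cGAS KO and STING KO were -0.11 and -0.09 for astrocyte markers, 0.02 and -0.02 for oligodendrocyte precursors, -0.07 and 0.18 for striatal interneurons, -0.53 and -0.17 for cortical neurons, and -0.05 and -0.04 for infiltrating monocytes and macrophages. Complement genes had medians of 0.17 and 0.09, with C4b at 43.3 ± 15.6 CPM in cGAS KO, 43.3 ± 10.5 CPM in STING KO and 27.2 ± 4.01 CPM in WT. Of 16 neutrophil markers 3, of 18 T and NK cell markers 4, and of 11 B cell markers 2 were expressed enough to be tested. Mitochondrially encoded genes were higher in cGAS KO than in WT in 13 of 13 members, with a median of 0.35 that camera did not call (adjusted p = 0.181), and called without those 3 libraries (median 0.30, adjusted p = 0.0376). The libraries overlapped, with a mean log2 CPM of this list of 9.492, 8.5 and 9.994 in cGAS KO replicates 1 to 3. In WT replicates 1 to 3 it was 9.216, 9.681 and 8.041. The highest value was that of cGAS KO replicate 3.

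The exchange of counts between mt-Nd3 and its nuclear copy may come from a base variant in the mitochondrial DNA of the STING KO line that sends reads to the copy, and the sum of both genes would then stay level. Against WT its log2 fold change was 0.15 (SE 0.40) over 9 libraries and -0.33 (SE 0.28) without the 3 of low complexity, and against cGAS KO -0.39 (SE 0.40) and -0.60 (SE 0.28), so a lower sum in addition stays open. A lower level of all mitochondrial transcripts as the source of the exchange is argued against by the other 12 mitochondrial protein genes. Against WT over 9 libraries their median was 0.028 in a range of -0.38 to 0.89. The list of 13 such genes, mt-Nd3 included, had a median of -0.42 against WT without the 3 libraries (camera adjusted p = 0.112). Against cGAS KO it was -0.36 over 9 libraries and -0.63 without the 3. A smaller general fall, of the size of the shift of the sum, thus stays open. Higher transcription of the whole nuclear copy is argued against by its other 5 pseudogenes, whose median was -0.17, in a range of -0.85 to 0.39. Reads over the position of T3C were not analysed here.

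The 3 libraries of low complexity, 1 per group, might hold fewer starting molecules. Of genes at 0.5 to 2 CPM in the other libraries, 9.78% to 22.1% had no count in these libraries against 0.030% to 0.995% in the other 6, so that the lowest of the 3 was 9.83 times the highest of the 6, which restates in part how the libraries were picked. Loss from the same genes stays open, since pairs of the 3 libraries shared at least 1.65 times the genes without a count that independent loss would give. Gene length and GC content accounted for a share of at most 0.20 of the variance of their deviations, and cannot be told apart, since WT replicate 2, among the other 6, had a share of 0.13. No biological explanation was tested since each group holds 1 such library.

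DNA carried along around an edited gene could change its neighbours. Within 10 Mb of Sting1, 7 of 175 genes (4.0%) had an unadjusted p under 0.05 in STING KO against WT, 2.49 times the share elsewhere (Fisher's exact p = 0.0251, two-sided), and the immediate early gene Egr1 was among them. Too few genes are involved to decide, and neighbouring genes are not independent. Within 10 Mb of Cgas, 2 of 126 genes had an unadjusted p under 0.05 in cGAS KO against WT, 0.78 times the share elsewhere. The exact 95% interval of the odds ratio ran from 0.093 to 2.90, just under the bound of 3. With so few genes, and an interval that takes neighbours as independent, a 3-fold excess is not decided here either.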
